A study of Homo sapiens with 18 samples.

How the data were processed

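RNA was sequenced on a NextSeq 500 from tumour cells of 3 oestrogen receptor positive breast cancer lines, MCF7, ZR751 and T47D, after 8 days in matrigel alone or with HS5 bone marrow stromal cells. Per the labels, the gel was broken down, stromal cells were depleted with microbeads, ERCC spike-in RNA was added to the lysates, and no drug was given. The 18 libraries were grouped by line and culture into 6 groups of 3 libraries. The labels do not say whether the replicates of a group came from separate cultures, and they give all libraries the same run name.

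The deposited table holds counts, made by the authors from reads aligned to hg19, with 60675 Ensembl gene rows and 4 summary rows per library. The aligner and the counting tool are not given in the sources used here, nor whether the counting used strand; DESeq2 is named by the authors without a version. Summary rows held 23.4 to 33.9% of the total per library: 12.1 to 22.8% unmapped, 2.92 to 6.86% outside annotated features, 6.67 to 9.35% ambiguous and 0 multimapping. The table has 0 ERCC rows, so spike-in counts were not used here and changes are relative to the other genes of a library, not per cell. Of the gene rows, 57055 were found in GENCODE 29, an annotation of GRCh38, while the reads were aligned to hg19, so no coordinates are printed. A symbol was found for 57043 rows, which hold 99.9% of gene counts.

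Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 15862 genes with 99.8% of gene counts and removed 19298 genes with a count. Libraries were scaled with TMM factors. A single quasi-likelihood model with robust dispersions was fitted to the 6 groups (12 residual degrees of freedom, common biological coefficient of variation 0.0798). Co-culture was tested against mono-culture in each line, as the average over the lines, and as a difference between lines (2 degrees of freedom). Benjamini-Hochberg adjusted p of 0.05 over all genes tested was the threshold for each. Counts expected for independent lists multiply the shares of called genes of the lines. Levels are CPM on TMM-scaled library sizes, except that the summed and mean levels of stromal markers use library sizes alone; the sum with TMM factors was added after the values were seen.

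Genes were named by a rule fixed before the data were examined. It takes, in each line, the 6 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and no overlap of the groups, the 6 largest rises among genes at 10 CPM or more in mono-culture, and the 4 members of each gene list with the smallest p. It adds the 8 largest shared rises and falls over the 3 lines by the smallest change, with at least 10 CPM in mono-culture (rises) or over the libraries (falls) of each line. It also adds the 8 smallest p for a difference between lines among genes at 10 CPM or more in mono-culture of each line, and 16 genes of the oestrogen axis, proliferation and stroma named in every case. The text names part of the list members that the rule gives, a choice made after their values were seen; ISG20, SQLE and H4C8, and ERBB3 in MCF7, were left out at that point. With no count in a group, a fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts it is a count ratio with a 95% counting interval. Any count ratio or bound stands for a gene whose fitted value depends on the prior count.

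The 31 gene lists with 863 members were also fixed in advance: early targets of the oestrogen receptor, luminal identity, basal and myoepithelial markers, growth factor receptors, the STAT3 and interleukin 6 response, the type I interferon response, the NF-kB and inflammatory response, antigen presentation, cytokines secreted by marrow stromal cells, TGF-beta response, regulators of epithelial to mesenchymal transition, ERK pathway output, bone marrow stromal, haematopoietic and endothelial markers, cell cycle G1/S and G2/M, p53 targets, apoptosis regulators, hypoxia and glycolysis, oxidative phosphorylation, cholesterol biosynthesis, the unfolded protein response, heat shock and dissociation-linked immediate early genes, mitochondrially encoded transcripts, cytosolic ribosomal proteins, replication-dependent histones, Notch and Wnt targets, stem cell and drug-efflux markers, cell adhesion and integrins, and bone-tropism and bone-matrix genes. They were written from general knowledge. Each was tested with camera at its preset correlation of 0.01, with p adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Pairwise differences of lists between lines, 10 further lists, and the epithelial genes KRT8, KRT18, KRT19, EPCAM and CDH1 were added after the values were seen.

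The mitochondrial share and the summed CPM of stromal markers were compared with two-sided exact permutation tests, over 20 labelings within a line and 8000 labelings within the 3 lines. With 3 against 3 libraries the smallest p is 0.1, and over the lines it is 0.00025.

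Depth and precision were checked on simulated data. Counts were drawn at the real depths with the dispersions estimated over all groups. In MCF7 co-culture 50 genes per size were changed, taken from genes with a mean of at least 50 counts in MCF7. The pipeline called 24% of genes changed 1.25-fold, 80% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 11 of 15343 unchanged genes. Genes with lower counts, and data with as many changed genes as found here, were not simulated. It called 0 of 15543 genes in the simulated ZR751 and T47D libraries, which held no change; DESeq2 1.42.0 called 145 of the 200 changed genes and 8 unchanged genes. Camera called the raised list and 0 of 30 unchanged lists. Genes were simulated independently of each other, so this check does not cover lists whose members vary together. Between replicates of a group the chi-square per gene was 1.50 to 11.7, where counting noise alone gives 1.

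Alternatives were relative log expression factors, library sizes alone, TMM over genes expressed in mono-culture, no low-count filter, a minimum of 10 CPM in mono-culture, DESeq2, a replicate block, a fit of each line alone, and leaving out each library. Leaving out mitochondrially encoded genes, the share of reads outside features as a covariate, and leaving out the 2 libraries with over 20% unmapped reads were added after the data were seen. Scripts ran in R and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.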

Results

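Transcript levels were measured by RNA sequencing in 3 oestrogen receptor positive breast cancer cell lines, MCF7, ZR751 and T47D. Each line was embedded in matrigel, a basement membrane gel, and grown for 8 days either alone (mono-culture) or together with HS5 cells (co-culture). HS5 is an immortalised human bone marrow stromal line. After the gel had been broken down, the stromal cells were depleted with magnetic beads and the tumour cells were sequenced, with no drug treatment. The title of the series asks how the bone marrow environment bears on the sensitivity of such cells to antioestrogens. The 18 libraries formed 6 groups of 3 libraries, and each holds between 5861621 and 9133028 counts on genes. Below, the error after a log2 fold change is its standard error and the error after a CPM value, a count scaled to library size with TMM factors unless library sizes alone are named, is an SD, with n = 3 libraries per group throughout. Gene calls are from edgeR's quasi-likelihood test at an adjusted p of 0.05 over 15862 genes, and list calls are from limma's camera. For the lists fixed in advance, the count of list members adjusted over the list alone equalled the count over all genes tested unless a separate count is given.

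The share of gene counts on mitochondrially encoded genes was higher in co-culture in each line. It went from 5.92 ± 0.91% to 13.2 ± 0.677% in MCF7, from 10.1 ± 0.992% to 33.1 ± 1.38% in ZR751, and from 16.8 ± 1.17% to 22.3 ± 2.02% in T47D. The mean log2 difference over the lines was 1.10, with an exact two-sided permutation p of 0.00025 within lines, the smallest that the 8000 labelings can give. Within a line, the exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Of the markers of bone marrow stromal cells, VIM, the intermediate filament of mesenchymal cells, was at 1.37 ± 0.387 CPM in MCF7 mono-culture and 1.22 ± 0.429 CPM in MCF7 co-culture. It was at 3.38 ± 0.798 and 4.61 ± 0.441 CPM in ZR751, and at 1.09 ± 0.297 and 0.813 ± 0.118 CPM in T47D. With library sizes alone, the summed CPM of the stromal marker list was 578 ± 9.13 in mono-culture and 636 ± 24.6 in co-culture of MCF7. It was 295 ± 32.2 and 193 ± 20.1 in ZR751, and 335 ± 1.60 and 376 ± 5.74 in T47D. Mono-culture held 346 CPM of the marker TIMP3 in MCF7 and 138 CPM in ZR751, so the sum does not measure left-over HS5 RNA alone. The log2 difference of the sum averaged −0.10 over the lines (exact two-sided permutation p = 0.344). With TMM factors it averaged 0.103 (p = 0.168 in the same exact test), at 0.297 in MCF7, −0.231 in ZR751 and 0.245 in T47D. The mean of log2(CPM + 1) over the markers, with library sizes alone, was higher in co-culture by 0.13 over the lines (exact two-sided permutation p = 0.0318), with differences of 0.198, −0.115 and 0.306 in MCF7, ZR751 and T47D.

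**Figure D1:**
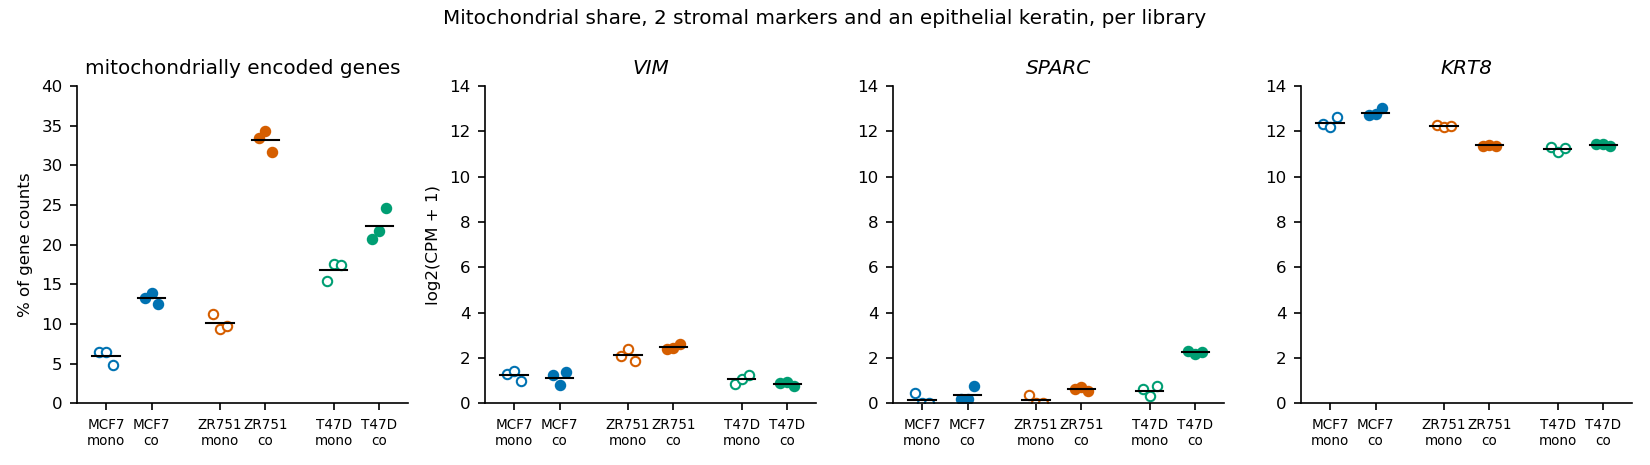
The first panel plots the percentage of gene counts on mitochondrially encoded genes in each library, and the others plot log2(CPM + 1) of the stromal markers VIM and SPARC and of KRT8, a keratin of luminal epithelial cells chosen after its values were seen. Points are libraries, open for mono-culture and filled for co-culture, and black lines are group means of the plotted values; the ZR751 co-culture mean of the first panel is 33.1%, and VIM stays far below KRT8 in every group.

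MCF7 cells grown with HS5 cells carried much more transcript of antimicrobial and acute-phase genes than MCF7 cells grown alone. S100A9 and S100A8, whose products form the antimicrobial protein calprotectin, rose 639-fold (log2 9.32 ± 0.23) and 292-fold (log2 8.19 ± 0.22). S100A9 went from 15.1 ± 3.43 to 9632 ± 1975 CPM. S100A7, which encodes psoriasin, rose 373-fold (log2 8.54 ± 0.16), and LTF, which encodes the iron-binding lactoferrin, rose 701-fold from 0.315 CPM. FGB, a fibrinogen chain, and the fatty acid receptor CD36 had no count in mono-culture and were at least 864-fold and 766-fold higher against a floor of 3 counts over the group. CLEC3A, a C-type lectin gene, had 2 counts in mono-culture and a count ratio of 1052 (counting interval 291 to 8693). The largest falls among genes with a mean of at least 10 CPM were in AFF3, a nuclear protein gene (log2 −4.07 ± 0.24), in the fatty acid elongase ELOVL2 (−3.91 ± 0.12), in TACC1 (−3.76), in SCUBE2 (−3.38 ± 0.14) and in AGR2, a luminal secretory pathway gene (−3.20 ± 0.11). ACSS1 (−3.13), SYNPO2 (−3.04) and DEPTOR (−3.02), an inhibitor of mTOR signalling, followed. Without co-culture replicate 2 the change in AFF3 was −4.69.

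In MCF7, 26 of the 29 measured members of the STAT3 and interleukin 6 response rose and 3 fell (median log2 1.17, adjusted p = 1.5e-35). Among them, LCN2, an iron-siderophore binding acute-phase gene, rose 127-fold. FGG and SAA1 had 1 and 2 counts in mono-culture, with count ratios of 3215 (counting interval 577 to 127000) and 1251 (counting interval 346 to 10330). Of the type I interferon response, 33 of 38 members rose and 1 fell (34 rose adjusted over the list alone; median log2 1.53, adjusted p = 9.77e-28). IFI27 rose 142-fold, IFI6 18.6-fold, LGALS3BP 16.4-fold and ISG15, a ubiquitin-like modifier, 16.3-fold. IFITM1, a membrane restriction factor outside that list, rose 18.7-fold. Of the antigen presentation list, 19 of 22 members rose and none fell, with 1 lower adjusted over the list alone (median log2 1.36, or 1.29 with members at their bound, adjusted p = 1.3e-07). HLA-B rose 3.27-fold, HLA-C 2.45-fold and TAPBP, a peptide loading factor, 2.29-fold. Of the NF-kB and inflammatory list, 19 of 26 rose and 3 fell (median log2 1.32, adjusted p = 1.17e-20), with the complement genes CFB and C3 72.2-fold and 36.8-fold higher. Of the cytokines that marrow stromal cells secrete, 12 of 16 rose and 1 fell (adjusted p = 0.00247). Left-over HS5 RNA was not tested as a source of the rise of this list. CXCL8 rose 7.78-fold to 12.5 CPM and IL11 8.68-fold to 11.4 CPM, while CXCL12 fell by 1.39. The SAA, S100A and HLA families hold near-identical copies whose reads the counting could split, so values of single members are uncertain.

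Cholesterol biosynthesis rose in MCF7 (15 higher, 3 lower of 24, and 16 higher and 4 lower adjusted over the list alone; median log2 0.67, adjusted p = 0.000421). TM7SF2, a sterol reductase, rose 2.66-fold and INSIG1, which restrains the same pathway, 2.17-fold. Heat shock and immediate early genes rose (17 higher, 7 lower of 36, and 18 higher adjusted over the list alone; median log2 0.21, adjusted p = 0.000432), with SOCS3 9.08-fold and ZFP36 2.98-fold higher. All 13 mitochondrially encoded transcripts rose (median log2 1.45, adjusted p = 1.37e-16, and adjusted p = 0.0629 with an estimated correlation), beside the rise in their share of counts to 13.2%. The luminal identity list fell (11 higher, 16 lower of 30; median log2 −0.27, adjusted p = 0.00227), with MUC1 3.75-fold higher and the prolactin receptor gene PRLR lower (log2 −1.61). Its adjusted p was 0.0786 with an estimated correlation. The basal list rose (9 higher, 4 lower of 17, adjusted p = 0.00611), with KRT17 23.3-fold and KRT81 4.76-fold higher. Its adjusted p was 0.0587 with an estimated correlation. ERK pathway output passed as higher (9 higher, 5 lower of 19, adjusted p = 0.0256), although its median log2 of 0.16 went to −0.001 with library sizes alone as scaling, with SPRY4 and DUSP6, feedback inhibitors of that pathway, 3.60-fold and 3.30-fold higher. Its adjusted p was 0.0629 with an estimated correlation.

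The remaining MCF7 calls on lists were also lost with an estimated correlation. Histone genes rose (8 higher, 1 lower of 12, adjusted p = 0.00354, and adjusted p = 0.0945 with an estimated correlation). The cell cycle G2/M list fell (1 higher, 18 lower of 37; median log2 −0.22, adjusted p = 0.00371, and adjusted p = 0.178 with an estimated correlation), with the topoisomerase gene TOP2A lower (−0.83). Hypoxia and glycolysis genes fell (8 higher, 19 lower of 37, and 10 higher adjusted over the list alone; median log2 −0.33, adjusted p = 0.0165, and adjusted p = 0.405 with an estimated correlation). NDRG1, a hypoxia-induced gene, fell by 1.52 and the lactate carrier SLC16A3 rose 3.13-fold. Cytosolic ribosomal protein genes fell (1 higher, 27 lower of 45, and 28 lower adjusted over the list alone; median log2 −0.39, adjusted p = 0.0017, and adjusted p = 0.656 with an estimated correlation). In all, 8097 of 15862 genes differed in MCF7, 4128 higher and 3969 lower in co-culture, with 1408 at least 2-fold higher and 976 at least 2-fold lower. With library sizes alone as scaling the median gene moved by −0.16 on the log2 scale, and 3008 genes were higher and 5422 lower.

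ZR751 cells showed the same antimicrobial genes at higher levels in co-culture, together with a larger interferon response and a loss of hypoxia-linked transcripts. S100A7 rose 419-fold (log2 8.71 ± 0.16), S100A9 302-fold (log2 8.24 ± 0.21) and S100A8 150-fold (log2 7.22 ± 0.20), the last from 198 ± 40.4 to 29560 ± 4675 CPM. SAA1, an acute-phase apolipoprotein, and SAA2 had no count in mono-culture and were at least 1365-fold and 520-fold higher. BPIFA1, an airway defence protein gene, went from 0.0473 to 428 CPM, a count ratio of 8572 (counting interval 1538 to 338600). CLEC3A and CD36 had count ratios of 8202 (counting interval 1472 to 324000) and 2891 (counting interval 518 to 114200). Apart from the small nuclear RNA RNU4-2, the largest falls among genes with a mean of at least 10 CPM were in GFRA1, a receptor for glial cell line-derived neurotrophic factor (log2 −6.85 ± 0.14), in the trefoil factor TFF3 (−6.31 ± 0.25) and in the progesterone receptor gene PGR (−4.98 ± 0.60). SYTL5 (−4.92), RGS22 (−4.88), IGFBP5 (−4.54) and METTL7A (−4.46) also fell. RNU4-2, whose level is highly variable between libraries, fell by 5.74 ± 2.06. Without mono-culture replicate 2 its change shrank to −2.41 (adjusted p = 0.39). Its adjusted p was 0.0714, 0.0779 and 0.0658 without co-culture replicate 1, 2 or 3. It was 0.134 in a fit of ZR751 alone and 0.0587 without the low-count filter. With the share of reads outside features as a covariate the change of RNU4-2 was −1.87 (adjusted p = 0.731). Without the 2 libraries with over 20% unmapped reads it was −2.37 (adjusted p = 0.181). Without mono-culture replicate 1 or co-culture replicate 3 its change was −6.34 or −6.44, and that of PGR without co-culture replicate 3 was −5.60. BPIFA4P is annotated as a pseudogene with at least 428-fold more counts than in mono-culture.

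In ZR751, 36 of the 38 measured interferon response members rose and 1 fell (median log2 3.14, adjusted p = 1.65e-78). IFI27 rose 322-fold, IFIT3, an RNA-binding antiviral gene, 85.2-fold, ISG15 33.2-fold and OAS2, an oligoadenylate synthetase, 22.2-fold. IFITM1 and IFI6 rose by log2 4.95 and 4.91. All 22 antigen presentation members rose (median log2 2.69, adjusted p = 2.06e-25), with the immunoproteasome subunits PSMB9 and PSMB8 87.4-fold and 19.1-fold and HLA-B 6.53-fold higher. Of the STAT3 and interleukin 6 response, 25 of 29 rose and 2 fell (26 rose adjusted over the list alone; median log2 1.78, adjusted p = 6.47e-33). LBP, which binds bacterial lipopolysaccharide, rose 676-fold, LCN2 401-fold and SOCS3, a feedback inhibitor of STAT3, 32.1-fold. Of the NF-kB and inflammatory list, 23 of 26 rose and none fell, with 1 lower adjusted over the list alone (median log2 2.07, adjusted p = 5.17e-27). CFB rose 782-fold, C3 85.1-fold and the superoxide dismutase SOD2 17.8-fold. Without mono-culture replicate 2 the log2 fold changes of CFB and IFI27 went from 9.61 and 8.33 to 10.28 and 8.98. Of the stromal cytokine list, 12 of 16 rose and 4 fell (median log2 2.82, adjusted p = 0.00558), with CCL5 69.3-fold higher at 22.0 CPM and CSF1 6.29-fold higher at 20.6 CPM.

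Hypoxia and glycolysis genes fell in ZR751 (3 higher, 31 lower of 37, and 32 lower adjusted over the list alone; median log2 −1.51, adjusted p = 1.23e-25). NDRG1 fell (log2 −3.69), as did the aldolase gene ALDOC (−3.04), the glucose carrier SLC2A1 (−2.60) and the pyruvate dehydrogenase kinase gene PDK1 (−2.22). The 13 mitochondrially encoded transcripts all rose (median log2 2.36, adjusted p = 5.77e-23), with MT-ND1 8.78-fold and MT-CYB 6.43-fold higher, as their share of counts reached 33.1%. Nuclear-encoded oxidative phosphorylation genes fell (4 higher, 27 lower of 42; median log2 −0.59, adjusted p = 0.00147, and adjusted p = 0.658 with an estimated correlation), with COX6C (−1.57) and SDHC (−1.49) lower. Cytosolic ribosomal protein genes fell (0 higher, 38 lower of 45; median log2 −0.69, adjusted p = 1.01e-05, and adjusted p = 0.631 with an estimated correlation). The G1/S list fell (1 higher, 22 lower of 32, and 3 higher adjusted over the list alone; median log2 −0.56, adjusted p = 0.00047, and adjusted p = 0.216 with an estimated correlation). GINS2 (−1.86) and MCM6 (−1.59), parts of the replicative helicase, fell. Early targets of the oestrogen receptor fell (12 higher, 25 lower of 45, and 13 higher and 26 lower adjusted over the list alone; median log2 −0.59, adjusted p = 0.00147, and adjusted p = 0.131 with an estimated correlation). The growth factor gene AREG fell by 4.01, while CA12 rose 4.79-fold. In all, 9917 genes differed in ZR751, 5001 higher and 4916 lower, with 2194 at least 2-fold higher and 1833 at least 2-fold lower. With library sizes alone the median gene moved by −0.38 on the log2 scale, and 2948 genes were higher and 7507 lower.

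T47D cells gained acute-phase transcripts that they barely carried in mono-culture. LBP rose 7207-fold (log2 12.81 ± 0.19), to 1789 ± 89.8 CPM, and the copper ferroxidase gene CP rose 6307-fold (log2 12.62 ± 0.20), to 1320 ± 64.1 CPM. LCN2 went from 0.117 to 678 ± 11.3 CPM, a count ratio of 5854 (counting interval 2003 to 28390), and FGG rose 2599-fold. SAA1 had 2 counts in mono-culture and a count ratio of 3071 (counting interval 850 to 25370), and SAA2 was at least 453-fold higher. Of genes with at least 10 CPM in mono-culture, the largest rises were in TM4SF18-AS1, an antisense transcript, at 19.8-fold, in KYNU, a kynurenine pathway enzyme, at 14.3-fold, in IFITM2 at 10.8-fold and in the amino acid carrier SLC7A5 at 9.72-fold. TNFAIP2 and RCAN1 rose 9.65-fold and 9.52-fold. HMGCS2, the mitochondrial enzyme that starts ketone body synthesis, went from 244 ± 16.5 to 0.0858 CPM, a count ratio of 2866 (counting interval 793 to 23670). SPINK5 (log2 −7.60), LRRN3 (−6.78), CCL28 (−6.25) and THBS1 (−5.67), an extracellular matrix glycoprotein gene, fell, as did GFRA1 (−5.64), NAALADL2 (−5.05) and IGFBP5 (−4.74). Without mono-culture replicate 3 the log2 fold changes of CP and FGG were 14.01 and 12.97, and without co-culture replicate 3 that of GFRA1 was −6.50. Because the counting is not stated to use strand, reads of TM4SF18-AS1 and of genes that overlap it cannot be told apart.

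In T47D, 24 of the 29 measured STAT3 and interleukin 6 response members rose and 2 fell (median log2 1.82, adjusted p = 5.3e-53), with FGB 1776-fold higher. Of the NF-kB and inflammatory list, 24 of 26 rose and 1 fell (median log2 3.15, or 2.62 with members at their bound, adjusted p = 5.3e-53), with C3 259-fold and CFB 229-fold higher. Of the antigen presentation list, 21 of 22 rose and none fell (median log2 1.85, adjusted p = 4.96e-20), with CD74, the class II invariant chain, 9.46-fold and HLA-F 6.93-fold higher. Of the type I interferon response, 20 of 38 rose and 4 fell (median log2 0.71, adjusted p = 0.00116). LGALS3BP rose 3.77-fold and the ubiquitin ligase gene HERC6 fell by 2.19. Of the stromal cytokine list, 10 of 16 were higher and 1 lower (median log2 3.16, or 1.61 with members at their bound), and the list was not past the threshold (adjusted p = 0.0612, and 0.0995 with an estimated correlation). Its adjusted p was 0.0483 without mono-culture replicate 1 and 0.0348, 0.0435 or 0.0487 without co-culture replicate 1, 2 or 3. ERK pathway output rose (13 higher, 1 lower of 19; median log2 0.89, adjusted p = 4.37e-08), with SPRY4 20.3-fold and ETV4 13.3-fold higher. The unfolded protein response list rose (21 higher, 3 lower of 27; median log2 0.64, adjusted p = 2.27e-10). DDIT3, a stress-induced transcription factor gene, rose 7.35-fold, and the amino acid synthesis genes ASNS and PSAT1 5.59-fold and 4.94-fold. The p53 target list rose (14 higher, 6 lower of 25, and 7 lower adjusted over the list alone; median log2 0.45, adjusted p = 0.00015), with GADD45A 22.5-fold, GDF15 12.8-fold and the cell cycle inhibitor CDKN1A 3.02-fold higher.

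Cholesterol biosynthesis fell in T47D (1 higher, 20 lower of 24, and 21 lower adjusted over the list alone; median log2 −0.80, adjusted p = 3.28e-07). HMGCS1 (−1.33), an enzyme of the pathway, and INSIG1 (−1.42) fell. Early targets of the oestrogen receptor fell (8 higher, 32 lower of 45; median log2 −0.53, adjusted p = 3.99e-10), with the scaffold gene PDZK1 (−4.14) and the trefoil factor TFF1 (−3.70) lower. The luminal identity list fell (7 higher, 16 lower of 30; median log2 −0.37, adjusted p = 0.000446), with PRLR (−2.82) and the androgen receptor gene AR (−2.68) lower. The G2/M list fell (2 higher, 27 lower of 37; median log2 −0.53, adjusted p = 9e-06), with ECT2 (−1.14) and PLK1 (−1.14), a mitotic kinase gene, lower. Hypoxia and glycolysis genes fell (6 higher, 27 lower of 37; median log2 −0.49, adjusted p = 0.000401, and adjusted p = 0.216 with an estimated correlation), although VEGFA, which encodes an angiogenic factor, rose 3.11-fold. Histone genes fell (0 higher, 7 lower of 12; median log2 −0.60, adjusted p = 0.0406, and adjusted p = 0.216 with an estimated correlation), with an adjusted p of 0.0553, 0.058 or 0.0591 without mono-culture replicate 2 or co-culture replicate 1 or 3. The stromal marker list passed as higher (12 higher, 5 lower of 26; median log2 0.23, adjusted p = 0.0419, and adjusted p = 0.194 with an estimated correlation), with an adjusted p of 0.0508 without co-culture replicate 3. NNMT went from no count to 9.04 CPM, at least 78.4-fold, LOX rose 4.18-fold to 14.7 CPM and FBLN1 rose 3.90-fold to 10.4 CPM. The haematopoietic marker list, with 4 measured members, passed as higher (3 higher, 1 lower; adjusted p = 0.0134), with CD34 at 13.4 CPM and CD14 at 6.68 CPM in co-culture. Of the 13 mitochondrially encoded transcripts 6 were higher and 0 lower (adjusted p = 0.0909, and 0.0419 without co-culture replicate 1), with their share of counts at 22.3% in co-culture. In all, 8565 genes differed in T47D, 3903 higher and 4662 lower, with 1356 at least 2-fold higher and 1290 at least 2-fold lower.

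**Figure D2:**
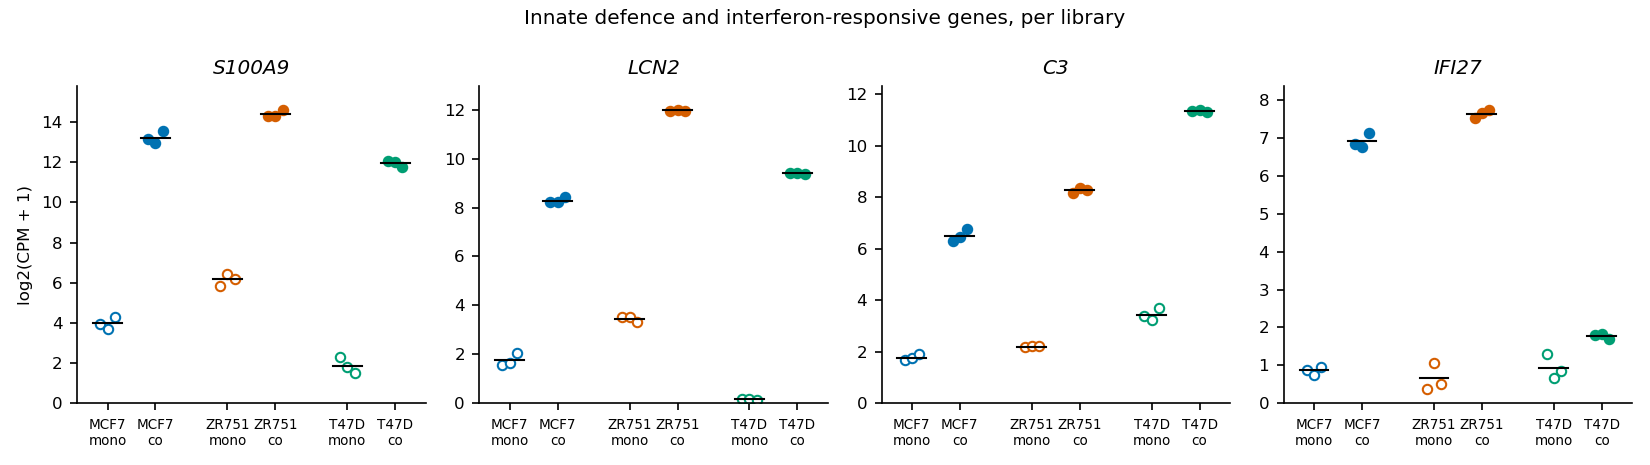
Each panel plots log2(CPM + 1) of the gene named above it in the 18 libraries; points are libraries, open for mono-culture and filled for co-culture, and black lines are group means of the plotted values. S100A9, LCN2 and C3 are higher in each co-culture library than in each mono-culture library of the same line, and IFI27 reaches 120 CPM in MCF7 and 198 CPM in ZR751 but 2.42 CPM in T47D co-culture.

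Transcripts of the oestrogen receptor itself were lower in co-culture in all 3 lines. ESR1 (ENSG00000091831) went from 105 ± 7.79 to 27.2 ± 5.98 CPM in MCF7, from 82.8 ± 6.26 to 26.6 ± 4.88 CPM in ZR751 and from 212 ± 6.41 to 57.5 ± 1.62 CPM in T47D. Its log2 fold changes were −1.92 ± 0.12, −1.64 ± 0.12 and −1.88 ± 0.11, and the test of a difference between lines gave an adjusted p of 0.262. Its target PGR fell (−2.61 ± 0.37, −4.98 ± 0.60 and −3.33 ± 0.26), and so did GREB1, an oestrogen-induced coactivator gene (−0.64 ± 0.09, −0.43 ± 0.09 and −0.53 ± 0.09). PDZK1 fell in MCF7 (−2.35 ± 0.32) and in ZR751 (−2.26 ± 0.33). Without co-culture replicate 2 the MCF7 changes of PGR and PDZK1 were −4.00 and −3.17, and without co-culture replicate 3 the ZR751 change of PGR was −5.60. TFF1, which encodes a secreted trefoil peptide, fell in ZR751 (−2.98 ± 0.11) and in T47D (−3.70 ± 0.13), while in MCF7 it was at 7337 ± 897 CPM in mono-culture and 7965 ± 1026 CPM in co-culture (adjusted p = 0.362). BCL2, an apoptosis inhibitor gene induced by oestrogen, fell in MCF7 (−2.56), ZR751 (−3.04) and T47D (−1.54). FOXA1, a pioneer factor for the receptor, fell in the same order (−0.65, −0.78 and −0.87). GATA3, a luminal transcription factor gene, rose 1.75-fold in MCF7 and 1.41-fold in ZR751 (adjusted p = 0.22 with library sizes alone) and fell by 0.90 in T47D. CCND1, the cyclin D1 gene, fell in MCF7 (−0.52) and ZR751 (−1.19) and rose 1.43-fold in T47D. MYC differed in ZR751, where it fell by 0.26, and had an adjusted p of 0.309 in MCF7 and 0.15 in T47D. These calls depended on the setting: with the share of reads outside features as a covariate the adjusted p of MYC was 0.346 in ZR751 (−0.123) and 0.0296 in T47D (0.195). It was 0.00661 in MCF7 with library sizes alone (−0.264) and 0.0126 in a fit of T47D alone (0.193). The proliferation marker MKI67 rose 1.60-fold in ZR751, fell by 0.80 in T47D and was at 94.4 and 97.9 CPM in MCF7 (adjusted p = 0.645). Over all early targets in MCF7, 13 were higher and 23 lower of 45, and the list was not past the threshold (adjusted p = 0.0947, and 0.048 or 0.0498 without mono-culture replicate 1 or 2).

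**Figure D3:**
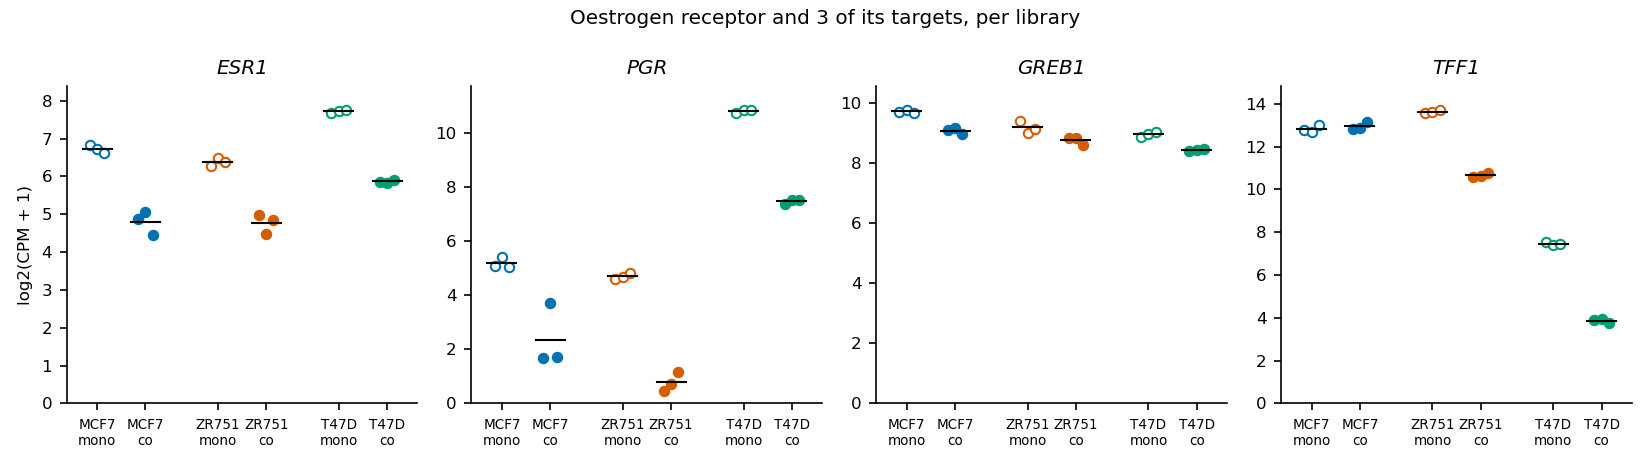
Each panel plots log2(CPM + 1) of the gene named above it in the 18 libraries; points are libraries, open for mono-culture and filled for co-culture, and black lines are group means of the plotted values. ESR1, PGR and GREB1 are lower in each co-culture library than in each mono-culture library of the same line, and the TFF1 libraries of MCF7 overlap, with means of 7337 CPM in mono-culture and 7965 CPM in co-culture.

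Over the 3 lines, 2566 genes were called in the same direction, 1311 higher and 1255 lower, against 320 and 362 for independent lists. Called in opposite directions were 981 genes between MCF7 and ZR751, 980 between MCF7 and T47D and 1841 between ZR751 and T47D. Independent lists would give 2530.7, 2189.9 and 2679.5. The 3 comparisons share no libraries, but they share 1 fit and its estimates of the spread, which the counts for independent lists leave out of account. At least 2-fold in each line, 353 genes were higher and 170 lower, against 16.6 and 9.2 for independent lists. Among genes with at least 10 CPM in mono-culture of each line, the largest shared rises by their smallest change were in CSTB, a cathepsin inhibitor gene, at 10.8-fold in MCF7, 12.2-fold in ZR751 and 6.99-fold in T47D, and in IFITM2 at 5.27-fold, 6.16-fold and 10.8-fold. SOD2 rose 4.54-fold, 17.8-fold and 5.91-fold, KYNU 4.31-fold, 6.80-fold and 14.3-fold, and CEBPB, a transcription factor gene of the acute-phase response, 4.25-fold, 7.56-fold and 6.14-fold. The heparin-binding growth factor gene MDK rose 3.81-fold, 4.13-fold and 3.92-fold, with an adjusted p of 0.734 for a difference between lines. LGALS3BP rose 16.4-fold, 16.5-fold and 3.77-fold, and CTSD, which encodes a lysosomal protease and is itself an oestrogen target, 6.15-fold, 5.60-fold and 3.52-fold. Besides PGR, the largest shared falls among genes with a mean of at least 10 CPM over the libraries of each line, ranked by their smallest change, were in TFF3 (−2.66, −6.31 and −4.05), GFRA1 (−2.43, −6.85 and −5.64) and ELOVL2 (−3.91, −2.35 and −2.62). NAALADL2 (−2.61, −2.21 and −5.05), KIF12 (−1.98, −3.27 and −3.70), IGFBP5 (−1.94, −4.54 and −4.74), an insulin-like growth factor binding protein gene, and DEPTOR (−3.02, −2.67 and −1.87) followed. Of the stromal genes named in advance, COL1A1 rose 1.90-fold in MCF7 and 2.86-fold in ZR751, to 82.5 and 83.0 CPM, and was at 80.2 and 84.7 CPM in T47D (adjusted p = 0.65). COL1A2 was at or below 1.56 CPM and SPARC at or below 3.77 CPM in each group. SPARC was at 0.24 to 0.70 CPM in T47D mono-culture libraries and at 3.58 to 3.90 CPM in T47D co-culture libraries. It was called higher in ZR751 (log2 2.28, adjusted p = 0.0465), but not with library sizes alone or DESeq2 (adjusted p = 0.0958 and 0.0927). COL1A2 had no count in ZR751 mono-culture, lay between 0.367 and 0.771 CPM in ZR751 co-culture libraries, and fell in T47D (−1.80). IL6 had no count in mono-culture and reached 0.54 ± 0.285, 3.69 ± 1.03 and 0.42 ± 0.19 CPM in MCF7, ZR751 and T47D co-culture.

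The size of the effect depended on the line for 10143 genes in the test of differences between lines. THBS1 rose 1.39-fold in MCF7 and fell in ZR751 (log2 −2.02) and T47D (−5.67). SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis, rose 1.75-fold in MCF7 and fell in ZR751 (−4.17) and T47D (−0.58). NUPR1, a stress-induced chromatin protein gene, fell by 2.90 in MCF7 and rose 2.21-fold in ZR751 and 4.01-fold in T47D. ERRFI1, a feedback inhibitor of the epidermal growth factor receptor, rose 1.54-fold in MCF7 and 6.64-fold in T47D and fell by 0.82 in ZR751. FN1, the fibronectin gene, rose 7.93-fold in T47D and fell by 0.27 in ZR751. Its 1.17-fold rise in MCF7 had an adjusted p of 0.0634, 0.0637 or 0.052 without mono-culture replicate 1 or 2 or co-culture replicate 3, of 0.492 with library sizes alone and of 0.0538 without the low-count filter. The carbonic anhydrase CA12 and the Golgi protein gene GOLM1 rose 2.52-fold and 3.51-fold in MCF7 and 4.79-fold and 7.18-fold in ZR751, and fell in T47D (−1.02 and −0.46). TM4SF18-AS1 rose 1.40-fold in MCF7 and fell by 1.23 in ZR751. Fold changes correlated across genes at r = 0.62 between MCF7 and ZR751, 0.438 between MCF7 and T47D and 0.413 between ZR751 and T47D. These correlations are over genes, which are not independent replicates.

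Lists were also compared between lines, in tests added after the data were seen. The interferon response was higher in ZR751 than in MCF7 (median difference in log2 fold change 1.75, adjusted p = 3.4e-20) and lower in T47D than in MCF7 (−0.81, adjusted p = 1.83e-05). Hypoxia and glycolysis genes fell further in ZR751 than in MCF7 (−1.23, adjusted p = 4.5e-30). Cholesterol biosynthesis differed between T47D and MCF7 by −1.20 (adjusted p = 9.34e-24) and between ZR751 and MCF7 by −0.78 (adjusted p = 7.48e-10). In T47D the unfolded protein response and p53 target lists lay above MCF7 by 0.78 (adjusted p = 3.5e-12) and 0.47 (adjusted p = 1.2e-07), and ERK pathway output by 1.22 (adjusted p = 1.22e-05). Histone genes lay below MCF7 by −1.58 (adjusted p = 4.49e-08). The early oestrogen targets fell further in T47D than in MCF7 (−0.31, adjusted p = 2.01e-06). Each of these differences kept an adjusted p under 0.05 with an estimated correlation.

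**Figure D4:**
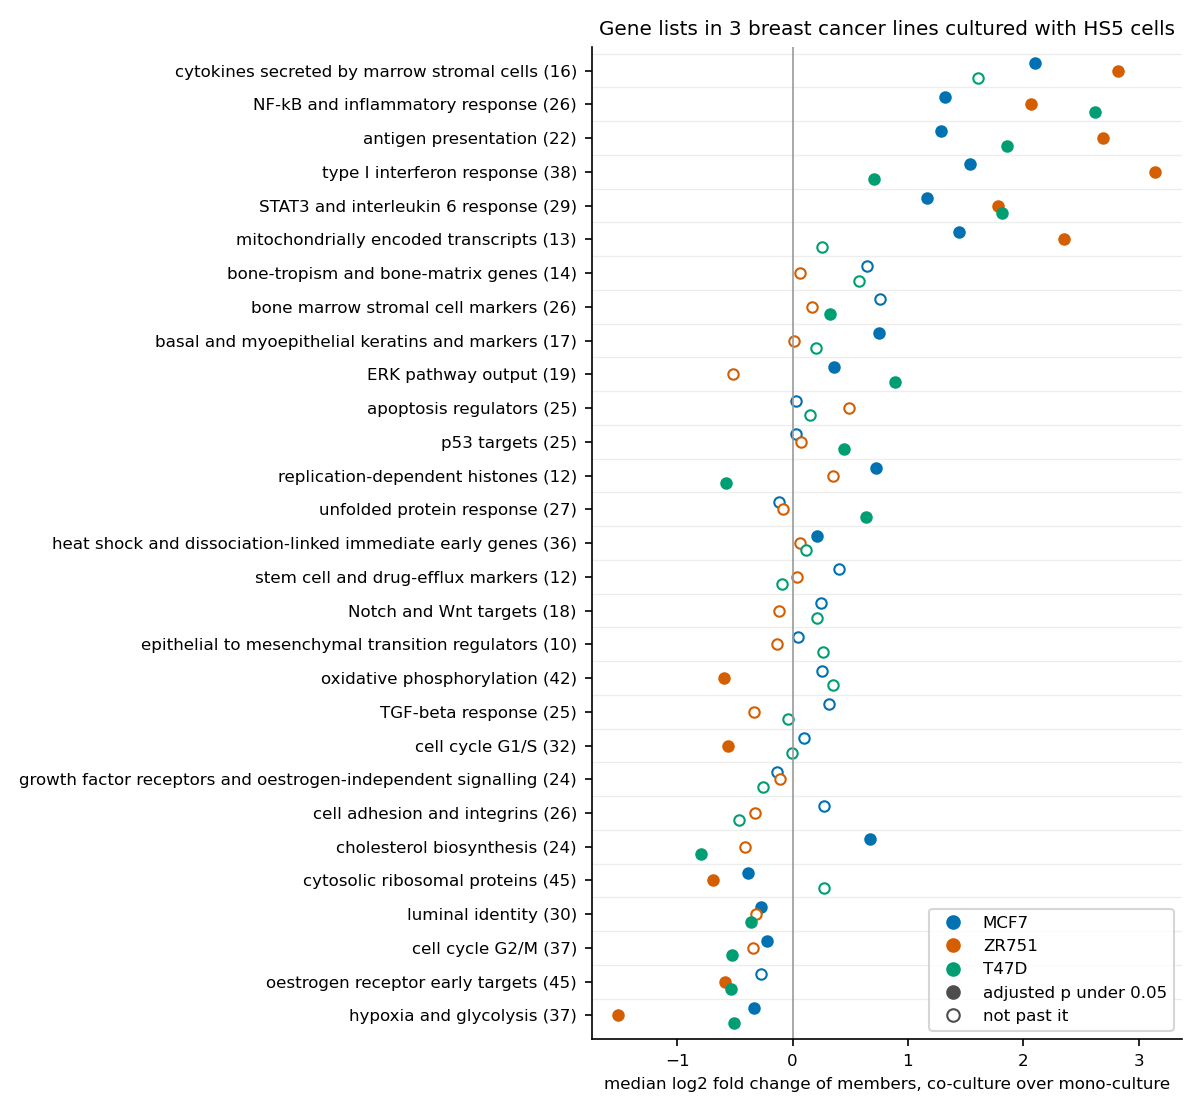
The horizontal axis is the median log2 fold change of the measured members of each gene list, co-culture over mono-culture, and the vertical axis names the list with its number of measured members. Points are coloured by line and filled where camera's adjusted p is under 0.05. Members with 3 counts or fewer in 1 group enter at their bound or count ratio, and those with 3 or fewer in both groups are left out of the median. Some medians therefore differ from the fitted ones in the text, such as ERK pathway output in MCF7, drawn at 0.362 and fitted at 0.156. Lists with under 5 measured members are left out. The interferon response lies at 3.14 in ZR751, 1.53 in MCF7 and 0.71 in T47D, and hypoxia and glycolysis at −1.51 in ZR751.

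Averaged over the lines, 10312 genes differed, 5055 higher and 5257 lower, and 16 of the 31 lists passed, 10 of them with an estimated correlation. The STAT3 and interleukin 6 response (median log2 1.33, adjusted p = 3.32e-69), the NF-kB and inflammatory list (2.10, adjusted p = 4.31e-51) and the antigen presentation list (1.89, adjusted p = 7.92e-23, 22 of 22 members higher) rose. Hypoxia and glycolysis genes (−0.62, adjusted p = 2.14e-15, 30 of 37 lower) and early oestrogen targets (−0.42, adjusted p = 2.66e-07, 33 of 45 lower) fell. With library sizes alone the split was 3234 higher and 7534 lower, and that of the genes called in all 3 lines was 777 higher and 2213 lower. Several lists passed in no single line. The smallest adjusted p over the lines was 0.0506 for the TGF-beta response (MCF7, 13 higher and 10 lower of 25, with ID1 8.98-fold higher and the receptor decoy BAMBI lower at −1.55; adjusted p of 0.0469, 0.0291, 0.0436 or 0.0418 without mono-culture replicate 3 or co-culture replicate 1, 2 or 3) and 0.0662 for apoptosis regulators (ZR751, 14 higher and 4 lower of 25, with BCL2L11 4.59-fold higher). It was 0.111 for regulators of epithelial to mesenchymal transition, 0.119 for cell adhesion and integrins, 0.211 for stem cell and drug-efflux markers and 0.213 for growth factor receptors. It was 0.268 for bone-tropism and bone-matrix genes, 0.401 for Notch and Wnt targets and 0.813 for endothelial markers, of which 3 were measured. Members of these lists moved in both directions. INSR, the insulin receptor gene, rose 2.36-fold, 7.87-fold and 7.60-fold in MCF7, ZR751 and T47D, while ERBB3 fell in T47D (−1.03). The adhesion genes ICAM1 and CD44 rose 28.2-fold and 6.18-fold in T47D, and MMP13, a collagenase gene, rose 10.4-fold in MCF7 and 13.6-fold in ZR751. Of the 124 tests of lists, 57 passed, and 36 passed with an estimated correlation. Each of 99 other splits of the libraries within the lines gave 25 to 49 list calls at the preset correlation and 0 to 6 with an estimated correlation. A list's median, mean and test differed in sign in 19 of the tests, and 0 of these passed.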

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

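The weighing of the mitochondrial transcripts, the splits of the libraries and the naming of genes called in opposite directions between lines were chosen after the results were seen; the test of differences between lines was planned. In that test, 10143 of 15862 genes changed by different amounts in the 3 lines. Of the 8 named by the rule for this test, the largest gaps between the highest and lowest log2 fold change were in THBS1 (6.141, MCF7 over T47D), TM4SF18-AS1 (5.532, T47D over ZR751), SPTSSB (4.969, MCF7 over ZR751) and NUPR1 (4.902, T47D over MCF7). ERRFI1 (3.555) and FN1 (3.261) were highest in T47D and lowest in ZR751, and GOLM1 (3.308) and CA12 (3.277) highest in ZR751 and lowest in T47D. Their adjusted p for a difference lay between 7.62e-25 and 1.06e-20.

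Other genes named in the report were called higher in a line and lower in another, with the difference tested in the same way. The antiviral gene OAS2 differed by 5.542 and HERC6 by 3.332, both highest in ZR751 and lowest in T47D. The stress gene DDIT3 differed by 4.388 (T47D over MCF7), ETV4, an output of the ERK pathway, by 4.37 (T47D over ZR751), and the respiratory chain subunit COX6C by 2.254 (T47D over ZR751). Among genes of luminal cells and their growth, CCND1 differed by 1.712 (T47D over ZR751), GATA3 by 1.705 (MCF7 over T47D), and MUC1 by 2.275 and MKI67 by 1.479 (both ZR751 over T47D). The sterol genes INSIG1 (2.541) and TM7SF2 (1.867) were highest in MCF7 and lowest in T47D. The matrix crosslinking gene LOX differed by 3.891 (T47D over ZR751). For 4 genes the gap rests on counts near 0 in a group, so its size depends on the prior count: CD36 (12.976, MCF7 over T47D), LRRN3 (11.496, MCF7 over T47D), COL1A2 (7.011, ZR751 over T47D) and KRT81 (4.319, MCF7 over T47D). KRT81 was called higher in MCF7 and lower in ZR751 (−1.78), while in T47D its 6 and 1 counts gave no call (−2.067, adjusted p = 0.112). Without T47D mono-culture or co-culture replicate 1 the T47D change was called, at −2.537 and −3.896 (adjusted p = 0.0437 and 0.041). LRRN3 in MCF7 was not called without co-culture replicate 2 (adjusted p = 0.23), where its log2 fold change of 4.72 became 2.47, and was 5.32 without co-culture replicate 1. COL1A2 in T47D was not called without co-culture replicate 3, with DESeq2 or with the share of reads outside features as a covariate (adjusted p = 0.0653, 0.0794 and 0.0886). Of 116 other named genes, 93 passed the test of differences between lines.

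Cholesterol biosynthesis was higher in MCF7 and lower in T47D, with a median difference of 1.202 (adjusted p = 9.34e-24), and histone genes likewise, with a difference of 1.583 (adjusted p = 4.49e-08). In MCF7 the sterol list had 15 members higher and 3 lower of 24, and in T47D 1 higher and 20 lower. The S-phase linked histone genes were called 8 higher and 1 lower of 12 in MCF7, and 0 higher and 7 lower in T47D. Both histone calls were lost with an estimated correlation (adjusted p = 0.0945 in MCF7 and 0.216 in T47D), and the T47D call also without mono-culture replicate 2 or co-culture replicate 1 or 3 (adjusted p = 0.0553, 0.058 and 0.0591), while the difference between the lines had an adjusted p of 0.00606 with an estimated correlation.

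A signal outside the gene counts also differed. The share of reads outside annotated features rose by 0.284 on the log2 scale over the lines (exact two-sided permutation p = 0.0335), from 3.26 ± 0.447% to 5.05 ± 0.518% in ZR751 and from 4.02 ± 0.3% to 4.70 ± 0.286% in T47D, and was 5.71 ± 1.24% and 5.67 ± 1.19% in MCF7. Each was measured in 3 libraries per group.

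Mitochondrially encoded transcripts rose as a list in MCF7 and ZR751 (adjusted p = 0.0629 and 0.0396 with an estimated correlation) but did not pass in T47D (6 of 13 called, adjusted p = 0.0909), and the difference of 0.871 between ZR751 and MCF7 had an adjusted p of 3.67e-06, or 0.239 with an estimated correlation. Scaling does not account for the rise, since their median log2 fold change was 1.281 or more in MCF7 and ZR751 with library sizes alone. Loss of cytoplasmic RNA from damaged cells could raise reads outside annotated features. Their log2 difference was −0.01 in MCF7, against a spread of 0.324 between libraries, and 0.634 in ZR751, against a spread of 0.174. In MCF7 this measure alone, in 3 libraries per group, does not exclude such a loss. Cytosolic ribosomal protein genes fell there (median −0.39, 1 higher and 27 lower of 45, adjusted p = 0.0017, or 0.656 with an estimated correlation). The nuclear retained RNAs were 2 higher and 0 lower of 8 in MCF7. In ZR751 this explanation stays open as well. There the nuclear retained RNAs, MALAT1 and NEAT1 among them, were 6 higher and 1 lower of 8 (7 higher adjusted over the list alone) without passing as a list (adjusted p = 0.0947). In ZR751 the nuclear-encoded respiratory chain genes fell by a median of −0.594, opposite in direction to a joint rise of the respiratory chain genes of both genomes. That fall had an adjusted p of 0.00147, or 0.658 with an estimated correlation. Since loss of cytoplasmic RNA stays open in ZR751, the fall does not settle the question there. A joint rise also stays open in MCF7 (median 0.253, 18 higher and 4 lower of 42, adjusted p = 0.0592, or 0.76 with an estimated correlation, and 0.0142, 0.0359 or 0.0121 without mono-culture replicate 3 or co-culture replicate 1 or 2).

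Calls were also counted over other splits of the libraries within each line. In a line there are 10 splits, too few for a share under 0.05. The real split gave 8097 genes in MCF7, 9917 in ZR751 and 8565 in T47D with edgeR, and the highest other split gave 0 in each. At an unadjusted p under 0.05 the real counts were 8949, 10437 and 9291 and the highest others 1601, 3267 and 532. Of 100 splits drawn over the 3 lines, 1, the real one, gave as many genes for the average (10312, highest other 3343), for the difference between lines (10143, highest other 4292), for genes in the same direction in all lines (2566, highest other 0, and 2889 against 6 at an unadjusted p under 0.05) and for lists (57, highest other 49, and 36 against 6 with an estimated correlation). Other splits mix the cultures, so a difference between cultures widens their spread and lowers their counts. The labels do not say whether the replicates of a group came from separate cultures. These counts therefore do not exclude a chance difference between single cultures. At the preset correlation every other split gave at least 25 list calls, so the count does not exclude chance for a given list call. Of the other splits, those that keep the real grouping of no line gave at most 0 genes for the average and for the difference between lines, and up to 42 list calls, or 0 with an estimated correlation.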

How the results depend on the processing

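Tests with mitochondrially encoded genes left out, with the share of reads outside features as a covariate, without the 2 libraries with over 20% unmapped reads, and of the stromal sum with TMM factors were chosen after the results were seen; the others were planned. The counts of called genes stayed within 1.5 times the reported counts under other scalings, without the low-count filter, with DESeq2, with a replicate block, in a fit of each line alone and under the added settings. The genes called were not all the same. With library sizes alone, 6977 of the 8097 calls in MCF7, 7864 of 9917 in ZR751 and 7995 of 8565 in T47D were shared in the same direction. With DESeq2, 7246 genes were called in MCF7, 9455 in ZR751, 7661 in T47D and 2174 in all 3 lines. Leaving out each library in turn gave 7339 to 7700 genes in MCF7, 9135 to 9951 in ZR751, 7732 to 8043 in T47D, 2334 to 2605 in all 3 lines and 55 to 62 list calls. Counts limited to genes at 10 CPM or more in mono-culture were lower for the average (6156) and for the difference between lines (6440), because fewer genes were tested. The number of list calls went from 57 to 36 with an estimated correlation, which widens the error of correlated lists, and to 107 with fry, which does not compare a list with other genes. The level of stromal markers reversed: with library sizes alone the summed CPM differed by −0.103 on the log2 scale over the lines and the mean of log2(CPM + 1) by 0.13 (exact two-sided permutation p = 0.0318). The sum follows its most abundant members. TIMP3 went from 138 to 37.4 CPM in ZR751, where the sum went from 295 to 193 CPM. It went from 346 to 166 CPM in MCF7 and from 3.66 to 11.5 CPM in T47D. The reversal was not tested without TIMP3. The sum with TMM factors differed by 0.103 (exact two-sided permutation p = 0.168).

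Labels give the groups the same replicate numbers. With a replicate block, 8645 genes were called in MCF7, 10268 in ZR751, 9139 in T47D, 10623 on average, 10625 for the difference between lines and 2805 in all 3 lines, with 59 list calls, 52 of them among the 57. Residuals of mono-culture and co-culture libraries with the same number correlated at 0.077, 0.229 and 0.245 in MCF7 and between −0.117 and 0.13 in the other lines. A library correlated best with the other culture's library of its own number in 6 of 6 cases in MCF7, 2 in ZR751 and 0 in T47D. In no line were all correlations judged high enough, so the main fit did not take the numbers to pair the libraries. For MCF7 the matches leave a shared effect of the replicate number open.

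Of the values for named genes under alternatives, 4461 kept their side of the threshold, 31 lost and 7 gained a call, and 0 reversed. Here and for lists, a change of sign where neither value passed the threshold counted as kept. Of list values, 413 were kept, 57 gained and 26 lost a call, and 0 reversed. Leaving out a library of the line changed 29 list calls: 10, 6 and 9 gained in MCF7, ZR751 and T47D and 4 lost in T47D. Scaling to ERCC spike-ins and the ERCC share were not run, since the table has no ERCC rows. Depth limits small changes: in the simulated MCF7 libraries 80% of genes changed 1.5-fold were called. These genes were taken from above a minimum mean count, so the share does not describe genes with few counts.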

Other observations

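All tests in this part were chosen after the results were seen. Further gene lists, written after the table of all genes was read, were tested in the same way, with p adjusted over these 10 lists. Because their members were chosen with the values in view, these p describe the lists and are no independent evidence of a change. Complement genes rose in each line (9 higher and 1 lower, 8 and 4, and 11 and 1 of 13 in MCF7, ZR751 and T47D; adjusted p = 1.76e-12, 2.07e-12 and 1.25e-18). Iron handling genes rose as well (10 higher and 3 lower, 11 and 2, and 12 and 5 of 19; adjusted p = 2.74e-12, 7.44e-16 and 1.18e-13), with LTF, LCN2 and CP among them, and with 4 lower in MCF7 adjusted over the list alone. Guanylate-binding and APOL genes rose, 8, 9 and 8 of 9 (median log2 1.76, 4.82 and 3.20; adjusted p = 0.000154, 1.08e-13 and 3.99e-10). These 3 lists kept an adjusted p under 0.05 with an estimated correlation. The S100A family rose in MCF7, 11 of 13 (12 adjusted over the list alone; adjusted p = 1.39e-28), and in T47D (8 higher, 3 lower; adjusted p = 4.8e-11). In ZR751 it was split, 6 higher and 6 lower, with a median of −0.39 against a test of higher (adjusted p = 3.71e-07, and 0.0628 with an estimated correlation).

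Amino acid synthesis and transport genes, which include ASNS, PSAT1 and SLC7A5, rose in T47D (17 higher and 0 lower of 19; median log2 1.03, adjusted p = 2.52e-16), and were 4 higher and 10 lower in MCF7 (5 higher adjusted over the list alone; adjusted p = 0.0926). Fatty acid uptake and synthesis genes rose in MCF7 (12 higher and 1 lower of 16, and 13 higher adjusted over the list alone; median log2 1.26, adjusted p = 5.03e-16) and ZR751 (8 higher and 3 lower, adjusted p = 2.91e-05), and were 5 higher and 8 lower in T47D (adjusted p = 0.135). Metallothioneins, with 3 measured, fell in ZR751 (adjusted p = 0.00166, and 0.0516 with an estimated correlation) and rose in T47D (adjusted p = 0.0187, and 0.128 with an estimated correlation). Mucins, with 4 measured, rose in MCF7 (adjusted p = 0.0315, and 0.106 with an estimated correlation). Carriers of glucose and lactate and nuclear retained RNAs passed in no line, with smallest adjusted p of 0.0947 and 0.0947 in ZR751.

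Acute-phase, inflammatory and antigen presentation genes rose in all 3 lines. RNA of HS5 cells left after the bead depletion does not account for the summed rise of these genes, though single members were not tested. With library sizes alone, the summed CPM of the 28 stromal markers under 10 CPM in mono-culture of each line differed by 0.213, −3.036 and 20.06 in MCF7, ZR751 and T47D, and that of the 84 genes of these lists by 4212.5, 8027.4 and 12382.2. With TMM factors the differences were 2.51, 2.909 and 21.73 for the markers and 4570.2, 11769.7 and 11976.2 for the lists. VIM was at 4.61 CPM or less, while the marker SPARC rose in T47D from 0.24 to 0.70 CPM in mono-culture libraries to 3.58 to 3.90 CPM in co-culture libraries. Nor does scaling account for the rise of these lists, since their lowest median was 1.008 with library sizes alone. The pattern may be a response of the tumour cells to HS5 cells, which cannot be separated from other effects of sharing a culture. Nor can it be separated from any handling that differed between the cultures. Whether mono-cultures also went through the bead depletion is not stated here. The cytokine IL6 stayed at 3.687 CPM or less, so that a small share of HS5 RNA and expression by tumour cells cannot be told apart for it. For the list of cytokines that marrow stromal cells secrete, left-over HS5 RNA was not tested as a source either.

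Transcripts of ESR1 and PGR fell in all 3 lines. Dilution of tumour cell RNA by other RNA does not account for this, since the lowest change of KRT8, KRT18, KRT19, EPCAM and CDH1 was −0.86, in ZR751, against −1.64 for ESR1. Nor does the choice among the 4 scalings, since the highest change of ESR1 and PGR was −1.616 over these and the lines. The alternatives raised the median gene by at most 0.042 (in T47D), so a larger error of scaling was not tested. Of the early targets, at least 8 were called higher in each line, and 5, WFS1, SUSD3, SERPINA1, CTSD and ZNF703, in all 3 lines, against 15 lower. Of all 15862 genes, 4128, 5001 and 3903 were called higher in MCF7, ZR751 and T47D. Some higher targets would therefore be found in any list, and the counts do not exclude lower activity of the receptor alone. Another explanation that stays untested is a joint action of a lower receptor level and of the inflammatory response on the early targets.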
